A study of Homo sapiens with 6 samples.

How the data were processed

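Messenger RNA was sequenced in 6 libraries of H1299 cells, 2 each of control, LMNB1 knockout and LMNB2 knockout, and the groups and replicate numbers were taken from the sample titles. Per the labels' protocols, 100 ng of total RNA was reverse transcribed with an oligo-dT primer, so transcripts without a poly(A) tail are poorly captured. The submitters' processing notes name the genome build GRCh38.p13 and the tools STAR 2.7.1a, RSEM 1.3.3, edgeR 3.36.0 and R 4.1.0. The role and order of the tools and the annotation release are not given in the sources used here. The authors deposited a table of expected counts per gene, in which 4.9% of the values are not whole numbers, and these estimated counts were rounded to whole numbers before testing. Expected counts split reads that match several genes, so values of near-identical copies (histones, clustered protocadherins, HLA genes, tubulins, GAGE genes) are uncertain. Whether strand was used in counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart. The authors also deposited 2 tables of their own comparisons, with log2 fold changes that the column name credits to edgeR. The p-value and adjusted p columns of the deposited tables end at 0.00996 and 0.0099 for the adjusted values, and no absolute log2 fold change lies under 0.5. The tables' 16 columns of values per sample were not used here.

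The count table held 60666 gene IDs, of which 42030 matched a gene symbol and 58420 a position in GENCODE 29 on GRCh38. Library totals lay between 9891230 and 11650590 counts. The ratio of chi-square to degrees of freedom between the libraries of a group was 11.149 in control, 3.902 in LMNB1 knockout and 2.831 in LMNB2 knockout, so in each group the libraries differed by more than sampling noise. The 10 most abundant genes held 7.82% to 11.63% of a library's counts.

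The design, the gene lists, the rule for named genes and the alternatives below, apart from those named as added, were fixed before the data were examined. Genes were kept by filterByExpr over the 3 groups (minimum count 10, minimum total count 15), which left 14829. A gene near silent in control was therefore kept only where a knockout raised it, which favours rises in lists of such genes. Counts were scaled by the trimmed mean of M values (TMM), with factors of 0.944 and 0.988 in control, 0.995 and 1.004 in LMNB1 knockout, and 1.036 in both LMNB2 knockout libraries. One robust quasi-likelihood model of edgeR 4.0.16 was fitted to all 6 libraries, without a replicate block and with 3 residual degrees of freedom. It shares the spread over the groups, although the control libraries differed more than the others. Its p-values may therefore be too small against control and too large between knockouts. With only the 4 libraries compared, 7423, 5786 and 8668 genes were called, against 8001, 6283 and 7534 in the shared fit. The common biological coefficient of variation was 0.088 and the median prior degrees of freedom 8.01. LMNB1 knockout and LMNB2 knockout were each compared with control and with each other, the last being the direct test of the difference between knockouts. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and all adjusted p values of single genes come from this test unless another is named. The standard error is the absolute log2 fold change divided by the square root of F. CPM values use the scaled library sizes. For genes with no count in a group the fold is a lower bound against a floor of 3 counts over the group. For genes with 1 to 3 counts in a group the ratio is given with its exact 95% counting interval.

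The named genes were LMNB1, LMNB2 and LMNA, and the 8 largest rises and falls against control (5 between knockouts). These had an average log2 CPM of at least 1, an informative symbol and both libraries of one group on the same side of both of the other. Of each gene list up to 4 members with the smallest adjusted p were taken where the list passed, and up to 2 otherwise. Some genes that the rule takes are not reported here. The 32 lists were nuclear lamina and envelope, nuclear pore, nuclear speckle and splicing, chromatin architecture, heterochromatin and Polycomb, replication-dependent histones, G1/S and DNA replication, G2/M and mitosis, p53 targets, senescence and secretory phenotype, interferon response, antigen presentation, NF-kB targets, epithelial, mesenchymal, collagen and extracellular matrix, YAP/TEAD and SRF targets, actin and cytoskeleton, cholesterol biosynthesis, unfolded protein and integrated stress response, hypoxia and glycolysis, oxidative phosphorylation, NRF2 targets with aldo-keto reductases, neuronal and neuroendocrine, clustered protocadherins, cancer-testis antigens, lung epithelial lineage, fibroblast, endothelial and blood markers, ribosomal proteins, and mitochondrially encoded genes. Of their genes, 7 belong to more than 1 list. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 32 lists, and again with an estimated correlation and with fry, which asks only whether a list's genes move one way. Counts of members called were made over all genes tested and adjusted over the list alone.

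The 23 chromosomes were tested with camera in the same way, and gene density was taken as the number of GENCODE 29 genes within 1 Mb. The agreement between knockouts was compared with 10 simulated pairs of unchanged groups against the same controls, and, after seeing the data, with each knockout set against a different control library. Alternatives were the relative log expression scaling, library size alone, no filter and a stricter filter (at least 1 CPM in 2 libraries and 50 counts), DESeq2 1.42.0, limma-voom, a replicate block, only the 4 libraries compared, no robust estimation, a 2-fold threshold, each library left out in turn, Spearman in place of Pearson correlation, and expressed genes only. Crossed control numbers in the block and removal of each chromosome's median were added after seeing the data. Ranges over the alternatives given for a list leave out the test with an estimated correlation, which is reported separately and gave larger adjusted p values. The software was R 4.3.3, with the package data.table in version 1.17.8.

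The edgeR step was tested on simulated data drawn from the means of the control libraries and the real library sizes, with 200 genes changed. For LMNB1 knockout against control it recovered 45.3% of the genes changed 1.5-fold, 66.2% of those changed 2-fold and 89.8% of those changed 4-fold among 13779 genes, and for LMNB2 knockout 46.2%, 70.3% and 88.5% among 13803 genes. It called 19 and 17 unchanged genes beside 133 and 136 recovered ones, more than the nominal 5%. Far more genes were called in the data (8001 and 6283) than were changed here, and the adjusted threshold depends on that share. These rates therefore do not give the power or the share of false calls in the data.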

Results

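Gene expression was measured by RNA sequencing in H1299 cells, an established human line from a non-small-cell lung carcinoma that lacks the tumour suppressor p53. LMNB1 or LMNB2 had been knocked out with guide RNAs, and these genes encode lamin B1 and lamin B2, the B-type intermediate filament proteins of the nuclear lamina. The study asked how B-type lamins organise chromatin in the nucleus through the lamina and nuclear speckles. The 6 libraries formed 3 groups of 2, namely control, LMNB1 knockout and LMNB2 knockout. All cells had been synchronised at the boundary of G1 and S phase with thymidine, which stalls DNA replication, at 2 mM for 18 h and again for 16 h after a release of 9 h. The libraries held 11650590 and 9891230 counts in control, 10157850 and 9962587 in LMNB1 knockout, and 10523195 and 11075339 in LMNB2 knockout. The mitochondrially encoded genes took 5.63% and 4.31% of the counts in control, 8.71% and 8.55% in LMNB1 knockout, and 7.18% and 6.64% in LMNB2 knockout. EEF1A1, a translation elongation factor, was the most abundant gene of every library, with 2.17% to 2.98% of the counts. The first principal component held 53.3% of the variance of log2 CPM, counts scaled to a common library total, and the second 32.2%. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. They also do not say whether each knockout was a single clone or a pool, so differences between clones cannot be told apart from loss of the gene. Intervals and floors cover counting error only.

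The targeted genes were lower in the libraries labelled as their knockouts. LMNB1 (ENSG00000113368; GRCh38 chromosome 5, 126776623 to 126837020, plus strand) stood at 172.5 ± 11.1 CPM in control (SD, n = 2). It stood at 6.177 ± 0.519 CPM in LMNB1 knockout (SD, n = 2), 3.58% of control, a log2 fold change of -4.80 (SE 0.12, adjusted p = 1.82e-09). LMNB2 (ENSG00000176619; chromosome 19, 2427638 to 2456996, minus strand) stood at 269.6 ± 29.5 CPM in control and at 39.89 ± 4.7 CPM in LMNB2 knockout (SD, n = 2 each), 14.8% of control. Its log2 fold change was -2.76 (SE 0.13, adjusted p = 8.41e-07). Each B-type lamin gene also fell in the knockout of the other. LMNB2 stood at 52.9% of control in LMNB1 knockout, a log2 fold change of -0.92 (SE 0.12, adjusted p = 0.000108), and LMNB1 at 63.9% in LMNB2 knockout, -0.65 (SE 0.09, adjusted p = 0.000242). LMNA (ENSG00000160789; chromosome 1, 156082573 to 156140089, plus strand), which encodes the A-type lamins, rose in both. It went from 505.8 ± 111 CPM in control to 1062 ± 162 CPM in LMNB1 knockout and 898.8 ± 46 CPM in LMNB2 knockout (SD, n = 2 each), log2 fold changes of 1.07 (SE 0.16, adjusted p = 0.00109) and 0.83 (SE 0.16, adjusted p = 0.00571). The LMNA value in LMNB2 knockout was 0.61 with an adjusted p of 0.0914 without control replicate 2, and over all alternatives its adjusted p ranged from 2.9e-08 to 0.0914. The counts cover each gene as a whole, and the positions of the guides are not given in the sources used here, so residual reads do not tell whether protein remained.

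**Figure D1:**
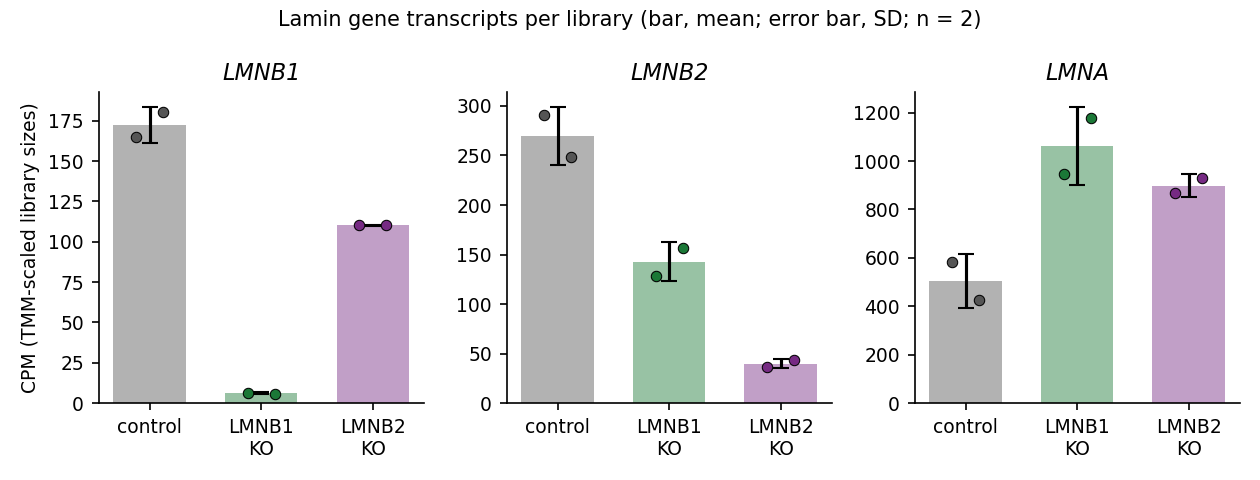
CPM of LMNB1, LMNB2 and LMNA in each of the 6 libraries (points), with the mean (bars) and SD (error bars) of each group of 2. LMNB1 lay at 6.544 and 5.81 CPM in LMNB1 knockout against 164.7 and 180.4 CPM in control, and LMNB2 at 36.57 and 43.21 CPM in LMNB2 knockout against 290.4 and 248.7 CPM in control.

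LMNB1 knockout was compared with control to ask which genes differ when lamin B1 is lost. CD22, a sialic-acid-binding receptor of B cells, had 1208 counts over the LMNB1 knockout libraries and 1 over the control libraries, a ratio of 1250 (95% interval 224 to 49400). The long noncoding RNA SWINGN was at least 37.9-fold higher and STRA6, a receptor for retinol-binding protein, at least 28.3-fold higher, since no control library had a read of either. NPAS2, a circadian transcription factor, rose by 7.24 on the log2 scale (SE 0.3, adjusted p = 3.87e-08) and MEGF6 by 6.52 (SE 0.21, adjusted p = 9.51e-09). The count ratio was 129 (43.6 to 626) for the pro-apoptotic BMF, 117 (20.5 to 4650) for the G protein subunit GNAO1 and 104 (28.4 to 864) for the stress-induced cytokine GDF15. Among the largest falls, the neural adhesion gene NTM was at least 46.8-fold lower and ZC4H2 at least 32.2-fold lower, with no read in LMNB1 knockout. The count ratio was 0.0185 (0.00221 to 0.0683) for the microfibril gene MFAP5 and 0.0272 (0.00324 to 0.102) for AMOT, a regulator of YAP. PNMA8A fell by 4.46 (SE 0.28, adjusted p = 3.98e-07), as did the hair keratin-associated KRTAP2-3 by 5.46 (SE 0.23, adjusted p = 1.02e-07), although the latter shares reads with near-identical copies and is uncertain. Of 14829 genes tested, 8001 (54%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3976 higher and 4025 lower. At least a 2-fold change as well was seen for 2872, of which 1787 were higher and 1085 lower.

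Genes of DNA replication and mitosis were lower in LMNB1 knockout. Of 49 G1/S and DNA replication genes, 45 fell (46 adjusted over the list alone) and 1 rose, with a median log2 fold change of -1.01. The replication clamp gene PCNA changed by -2.12 (SE 0.09), the helicase subunit MCM4 by -1.69 (SE 0.08), the origin-licensing factor CDC6 by -1.88 (SE 0.1) and thymidylate synthase TYMS by -1.57 (SE 0.08). Camera gave this list an adjusted p of 4.24e-24, and an adjusted p of 0.0744 with an estimated correlation. Of 40 G2/M and mitosis genes, 36 fell (38 adjusted over the list alone) and none rose (1 adjusted over the list alone), with a median of -1.05. CDC20, an activator of the anaphase-promoting complex, changed by -1.78 (SE 0.09), the kinase gene AURKA by -1.50 (SE 0.08) and the checkpoint kinase gene BUB1 by -1.68 (SE 0.11). Camera gave an adjusted p of 1.62e-21, and 0.206 with an estimated correlation. Nuclear pore genes fell in 25 of 27 cases and rose in 1, the same adjusted over the list alone, with a median of -0.66 (camera adjusted p = 3.9e-08; adjusted p = 0.317 with an estimated correlation). NUP93 changed by -1.72 (SE 0.08) and SEH1L by -1.49 (SE 0.09), both scaffold nucleoporins. Of 23 chromatin architecture genes, which encode cohesin, condensin and CTCF among others, 17 fell (18 adjusted over the list alone) and 2 rose, with a median of -0.76 (camera adjusted p = 1.77e-06; adjusted p = 0.448 with an estimated correlation). The condensin genes NCAPG and NCAPH changed by -1.45 (SE 0.08) and -1.50 (SE 0.11).

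Most called members of the cholesterol, cytoskeletal, heterochromatin and oxidative phosphorylation lists were lower as well, the last holding only nuclear-encoded genes. Of 24 tested genes of cholesterol biosynthesis, 15 fell (16 adjusted over the list alone) and 2 rose, median -0.74, with MSMO1 at -1.75 (SE 0.09) and HMGCS1, an early enzyme of the pathway, at -1.51 (SE 0.08). Camera gave an adjusted p of 3.9e-08, and 0.119 with an estimated correlation. Of 26 actin and cytoskeleton genes, 14 fell and 6 rose, with the same counts adjusted over the list alone and a median of -0.30. The tubulin genes TUBA1B and TUBB changed by -2.25 (SE 0.09) and -1.60 (SE 0.08), which share reads with close paralogs, and the actin-sequestering TMSB4X by 2.05 (SE 0.09). The list's camera adjusted p was 0.00474, with 0.434 as the adjusted p with an estimated correlation. It was 0.0538 with each chromosome's median removed, in a range of 1.97e-05 to 0.0538 over the alternatives other than the estimated correlation. Of 33 heterochromatin and Polycomb genes, 18 fell and 7 rose, also adjusted over the list alone, with a median of -0.36 (camera adjusted p = 0.0271; adjusted p = 0.206 with an estimated correlation). The maintenance DNA methyltransferase DNMT1 changed by -1.38 (SE 0.08), CBX5, which encodes HP1 alpha, by -1.33 (SE 0.09) and the Polycomb ubiquitin ligase gene RING1 by 1.10 (SE 0.12). Of 40 oxidative phosphorylation genes, 18 fell and 3 rose (6 with library size alone), also adjusted over the list alone, with a median of -0.20, and the ATP synthase genes ATP5F1A and ATP5F1B changed by -1.05 (SE 0.07) and -1.03 (SE 0.08). Camera gave this list an adjusted p of 0.0319, and 0.774 with an estimated correlation. Without control replicate 1 its median was -0.14 and its adjusted p 0.275, in a range of 0.000887 to 0.275 over the alternatives.

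Clustered protocadherin, matrix, secretory and immune genes were higher in LMNB1 knockout. Of 42 listed protocadherins, adhesion proteins whose promoters are chosen in neurons, 19 were tested. Of these, 18 rose (19 adjusted over the list alone) and none fell, with a median of 2.79. Camera gave an adjusted p of 2.44e-06, and 0.206 with an estimated correlation. Members near silent in control passed the filter only where a knockout raised them, so for those a fall could not be seen. As clustered genes the members are also not independent. PCDHGC3 changed by 3.67 (SE 0.19) and PCDHB14 by 3.23 (SE 0.29), though shared exons and similar sequences make single members uncertain. Of 18 tested senescence and secretory genes, 13 rose (14 adjusted over the list alone) and 2 fell, with a median of 1.78. The cell cycle inhibitor CDKN2B changed by 2.5 (SE 0.12), the cytokine LIF by 2.10 (SE 0.11) and SERPINE2, a protease inhibitor gene, by 2.63 (SE 0.12). Camera gave an adjusted p of 1.08e-07, and 0.206 with an estimated correlation. Of 25 collagen and extracellular matrix genes, 15 rose and 6 fell, also adjusted over the list alone, with a median of 1.02 (camera adjusted p = 1.2e-05; adjusted p = 0.206 with an estimated correlation). COL6A1 and COL13A1 changed by 5.27 (SE 0.2) and 4.76 (SE 0.16), and the fibrillin gene FBN2 by -3.44 (SE 0.22). Of 20 tested replication-dependent histone genes, whose main transcripts carry no poly(A) tail and are poorly caught by oligo-dT, 11 rose and none fell, also adjusted over the list alone, with a median of 1.32 (camera adjusted p = 0.00128; adjusted p = 0.211 with an estimated correlation). H2AC6 changed by 2.03 (SE 0.11) and H2BC21 by 2.42 (SE 0.17), which have near-identical copies.

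Of 17 antigen presentation genes, 13 rose and 1 fell, also adjusted over the list alone, with a median of 0.96, led by B2M (1.02, SE 0.08), the shared chain of class I molecules, and their transcriptional activator NLRC5 (2.17, SE 0.18). Camera gave an adjusted p of 0.000176, and 0.206 with an estimated correlation. The NF-kB targets had the same adjusted p values, 0.000176 and 0.206 with an estimated correlation. Of these 16 genes 13 rose and 2 fell, also adjusted over the list alone, with a median of 0.87, IER3 at 1.65 (SE 0.11) and NFKB2 at 1.01 (SE 0.09). Of 31 interferon response genes, 18 rose and 5 fell (6 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 0.0186; adjusted p = 0.206 with an estimated correlation). STING1, the adaptor that senses cyclic dinucleotides, changed by 3.27 (SE 0.16) and SAMD9L by 1.52 (SE 0.17). OASL, an antiviral oligoadenylate synthetase-like gene, had a count ratio of 56.9 (9.79 to 2290). Of 13 mitochondrially encoded genes, 11 rose and none fell (1 adjusted over the list alone), with a median of 0.63 (0.87 without control replicate 1, 0.40 without control replicate 2), MT-CO1 at 1.00 (SE 0.12) and MT-ND4 at 1.17 (SE 0.16). Camera gave an adjusted p of 0.00564, and 0.643 with an estimated correlation.

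The other 16 lists did not pass the test in LMNB1 knockout. Among the 22 nuclear lamina and envelope genes, 8 rose and 7 fell, also adjusted over the list alone, with a median of 0.12 (camera adjusted p = 0.596). Over the alternatives this median ranged from -0.025 to 0.167. The nesprin gene SYNE3 changed by 4.02 (SE 0.19). Among the 27 nuclear speckle and splicing genes, 8 rose and 14 fell, also adjusted over the list alone, with an adjusted p of 0.883 and a median of -0.27. NEAT1, the scaffold RNA of paraspeckles, changed by 1.80 (SE 0.09). Of 22 p53 targets 6 rose and 8 fell (camera adjusted p = 0.876), and the inhibitor CDKN1A changed by 1.47 (SE 0.1) in these p53-null cells. Adjusted p values were 0.0695 for mesenchymal genes (13 rose, 7 fell; TNC 4, SE 0.19), 0.471 for epithelial genes (5 rose, 3 fell; MUC1 1.56, SE 0.25) and 0.743 for YAP/TEAD and SRF targets (10 rose, 12 fell; EGR1 2.95, SE 0.11). They were 0.0928 for the unfolded protein and integrated stress response (13 rose, 9 fell; SESN2 1.56, SE 0.11), 0.105 for hypoxia and glycolysis (7 rose, 15 fell; ADM -2.52, SE 0.16) and 0.602 for NRF2 targets (9 rose, 6 fell; ABCC3 4.36, SE 0.2). They were 0.789 for neuronal genes (5 rose, 6 fell; SYT1 1.58, SE 0.15), 0.743 for cancer-testis antigens (5 rose, 5 fell; XAGE1A 1.09, SE 0.09), 0.108 for the lung lineage (3 rose, 1 fell; SOX9 1.76, SE 0.09) and 0.0848 for the 57 ribosomal proteins (20 rose, 2 fell; 19 and 2 adjusted over the list alone). Of markers of other cell types, COL1A1 of fibroblasts (2.55, SE 0.26) and ITGAM of blood cells (1.31, SE 0.16) rose, while the endothelial ESAM stood at 0.87 (SE 0.39, adjusted p = 0.0771) and CD68 at -0.15 (SE 0.11, adjusted p = 0.267). Few listed genes were tested: 1 of 10 for fibroblasts, 2 of 15 for blood and 1 of 10 for endothelium, and 6 of 24 for the lung lineage. Camera adjusted p values of these marker lists were 0.108 for fibroblasts, 0.528 for blood and 0.743 for endothelium. CD68 had a log2 fold change of -0.34 and an adjusted p of 0.0444 without LMNB1 knockout replicate 1, in a range of 0.0444 to 0.979 over the alternatives.

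No list of this comparison passed the threshold with an estimated correlation, where the smallest adjusted p was 0.0744. Adjusting over the list alone added at most 1 gene called higher and 2 called lower to a list. With library size alone as the scaling, the ribosomal list passed (median 0.195, camera adjusted p = 0.034). Without control replicate 1 the ribosomal list passed (median 0.34, adjusted p = 1.94e-05, range over the alternatives 1.94e-05 to 0.608), as did the stress response list (0.18, adjusted p = 0.0454, range 0.00494 to 0.47). Without control replicate 2 the hypoxia list passed (-0.43, adjusted p = 0.0215, range 0.0095 to 0.223). The median and the test had opposite signs for p53 targets (median -0.17), YAP/TEAD and SRF targets (-0.11) and neuronal genes (0.08). The median and the mean differed in sign for the speckle list (-0.27 and 0.04) and the cancer-testis list (-0.24 and 0.25).

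LMNB2 knockout was compared with control to ask the same of lamin B2. STRA6 was at least 15.2-fold higher and SWINGN at least 8.98-fold higher than in control, where neither had a read. The count ratio was 171 (30.3 to 6790) for OASL, 163 (28.8 to 6460) for CD22, 126 (34.5 to 1040) for the growth factor-binding gene IGFBP4, 117 (20.6 to 4660) for the channel subunit gene CACNG4 and 97.5 (17.1 to 3890) for the prostaglandin transporter gene SLCO2A1. DCLK1, a microtubule-binding kinase gene, rose by 6.35 on the log2 scale (SE 0.35, adjusted p = 9.49e-07). Among the falls, GSPT2, a translation termination factor gene, had a count ratio of 0.0139 (0.000346 to 0.0799). The chemokine gene CXCL2 fell by 4.13 (SE 0.11, adjusted p = 1.34e-08), the transcription factor gene STAT6 by 3.83 (SE 0.21, adjusted p = 9.18e-07), the growth factor gene FGF5 by 3.33 (SE 0.11, adjusted p = 2.09e-08), TMEM88 by 4.35 (SE 0.33, adjusted p = 6.91e-06) and WDR72 by 3.17 (SE 0.29, adjusted p = 1.7e-05). OR51B5 and the embryonic globin gene HBE1 had log2 fold changes of -5.50 (SE 0.25) and -5.31 (SE 0.29), but their annotated extents overlap, so reads of one may count for the other. Of 14829 genes, 6283 (42.4%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3116 higher and 3167 lower, and 1699 also changed at least 2-fold, 1314 higher and 385 lower. The count was 4080 without LMNB2 knockout replicate 1 and 3541 without replicate 2. With library size alone as the scaling, the median of all genes moved by 0.102 and 63.2% of 5953 calls were higher, against 49.6% of the calls above, so directions of small changes are relative to the scaling.

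Most ribosomal protein genes, and most called members of the nuclear-encoded oxidative phosphorylation list, were lower in LMNB2 knockout. Of 57 ribosomal protein genes, 39 fell (40 adjusted over the list alone) and none rose, with a median of -0.35 (camera adjusted p = 9.23e-09; adjusted p = 0.486 with an estimated correlation). RPS24 changed by -0.80 (SE 0.08) and RPL5 by -0.82 (SE 0.09). Of 40 oxidative phosphorylation genes, 20 fell and 1 rose, also adjusted over the list alone, with a median of -0.31 (camera adjusted p = 4.53e-05; adjusted p = 0.486 with an estimated correlation). CYC1, which encodes cytochrome c1, changed by -1.18 (SE 0.1) and ATP5PB by -0.99 (SE 0.08). Of 27 nuclear pore genes, 13 fell (17 adjusted over the list alone; 6 with library size alone, median -0.16) and none rose, median -0.27, with the channel nucleoporin gene NUP54 at -1.45 (SE 0.1) (camera adjusted p = 0.000812; adjusted p = 0.486 with an estimated correlation). Of 23 chromatin architecture genes, 11 fell and 2 rose, also adjusted over the list alone, median -0.27, with the cohesin gene SMC3 at -1.10 (SE 0.09) (camera adjusted p = 0.0043; adjusted p = 0.51 with an estimated correlation). Of 40 G2/M genes, 19 fell and 5 rose, also adjusted over the list alone, median -0.23 (14 and 7, median -0.13, with library size alone), with the proliferation marker MKI67 at -1.14 (SE 0.1) and UBE2C, a ubiquitin-conjugating enzyme gene of mitosis, at 0.82 (SE 0.07) (camera adjusted p = 0.00511; adjusted p = 0.486 with an estimated correlation). Of 33 heterochromatin and Polycomb genes, 16 fell and 2 rose (19 and 3 adjusted over the list alone), median -0.24, with CBX5 at -0.62 (SE 0.09) (camera adjusted p = 0.0327; adjusted p = 0.367 with an estimated correlation). With library size alone 8 of the 33 fell and 4 rose, with a median of -0.14 and an adjusted p of 0.0542, in a range of 0.00143 to 0.0542 over the alternatives. Sizes depended on the control library: without control replicate 1 or 2, medians were -0.20 or -0.53 for ribosomal proteins, -0.16 or -0.43 for oxidative phosphorylation and -0.47 or -0.09 for chromatin architecture.

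The G1/S, speckle and cancer-testis lists passed with lower medians in LMNB2 knockout, but not under every alternative. Of 49 G1/S and DNA replication genes, 19 fell (20 adjusted over the list alone) and 6 rose, with a median of -0.12 (camera adjusted p = 0.0466; adjusted p = 0.379 with an estimated correlation), the cyclin gene CCNE2 at -0.96 (SE 0.13) and the ribonucleotide reductase gene RRM2 at -0.64 (SE 0.09). Its adjusted p was 0.0671 without control replicate 1, 0.0681 without LMNB2 knockout replicate 2 and 0.101 with library size alone, in a range of 0.00609 to 0.101. With library size alone 14 fell and 7 rose, with a median of -0.016. Of 27 speckle and splicing genes, 13 fell and 3 rose (4 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.0466; adjusted p = 0.486 with an estimated correlation), PNN, which encodes pinin, at -1.01 (SE 0.08) and the splicing kinase gene CLK1 at 1.19 (SE 0.1). Its adjusted p was 0.256 without control replicate 2, 0.11 without LMNB2 knockout replicate 2 and 0.056 with a replicate block, in a range of 0.0299 to 0.256, and its median was -0.091 with library size alone. Of 16 cancer-testis antigens, which are normally germline genes, 6 fell (7 adjusted over the list alone) and 2 rose, with a median of -0.33 and a mean of 0.16 (camera adjusted p = 0.0287; adjusted p = 0.486 with an estimated correlation). GAGE1 changed by -2.99 (SE 0.19), although its copies are nearly identical, MAGEA4 by -0.78 (SE 0.09) and MAGEA1 by 3.25 (SE 0.36). Without control replicate 1 the median was -0.19 and the adjusted p 0.054, in a range of 0.000305 to 0.054.

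Matrix, mesenchymal, antigen presentation and interferon genes were higher in LMNB2 knockout. Of 25 collagen and extracellular matrix genes, 17 rose (18 adjusted over the list alone) and 5 fell, with a median of 0.79 (camera adjusted p = 9.24e-09; adjusted p = 0.355 with an estimated correlation). COL6A1 changed by 4.44 (SE 0.2) and the laminin gene LAMB1 by 1.59 (SE 0.09). Of 26 mesenchymal genes, 14 rose (16 adjusted over the list alone) and 2 fell, with a median of 0.41 (camera adjusted p = 3.1e-06; adjusted p = 0.367 with an estimated correlation). The matrix gene THBS1 changed by 2.43 (SE 0.12), the calcium-binding S100A4 by 3.72 (SE 0.26) and the integrin gene ITGB3 by 3.40 (SE 0.28). Of 17 antigen presentation genes, 10 rose (11 adjusted over the list alone) and 2 fell, median 0.79, with B2M at 1.51 (SE 0.08) and NLRC5 at 2.26 (SE 0.18) (camera adjusted p = 4.99e-06; adjusted p = 0.355 with an estimated correlation). Of 31 interferon response genes, 18 rose and 2 fell, also adjusted over the list alone, median 0.72, with STING1 at 2.46 (SE 0.16) and the antiviral IFIT2 at 2.40 (SE 0.21) (camera adjusted p = 3.87e-05; adjusted p = 0.355 with an estimated correlation). The histone list had the same camera adjusted p, 3.87e-05, and 0.367 with an estimated correlation: 12 of 20 rose and none fell, also adjusted over the list alone, with a median of 1.09 and H2BC21 at 2.63 (SE 0.16). Of 18 senescence and secretory genes, 13 rose and 3 fell, also adjusted over the list alone, median 1.01, with IGFBP3 at 3.42 (SE 0.18) and CXCL2 at -4.13 (camera adjusted p = 0.000875; adjusted p = 0.379 with an estimated correlation).

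The epithelial, protocadherin, mitochondrial and blood marker lists passed with less margin, the last with only 2 of 15 listed genes tested. Of 14 epithelial genes, 9 rose and 2 fell (3 adjusted over the list alone), median 0.93, with the tight junction gene CLDN4 at 2.20 (SE 0.35) and the desmosomal DSP at -1.01 (SE 0.11) (camera adjusted p = 0.0327; adjusted p = 0.367 with an estimated correlation). The list's adjusted p was 0.0511 without control replicate 2, in a range of 0.00678 to 0.0816. Of 19 protocadherins, 8 rose (9 adjusted over the list alone) and none fell, median 1.23, with PCDHGC3 at 2.36 (SE 0.2). Camera gave these genes an adjusted p of 0.0384, and 0.486 with an estimated correlation. The filter limits falls of these genes here as well. Their adjusted p was 0.154 without control replicate 1, 0.0515 without LMNB1 knockout replicate 1 and 0.104 without LMNB2 knockout replicate 2, in a range of 0.00234 to 0.154. Of 13 mitochondrially encoded genes, 5 rose (7 adjusted over the list alone; 11 with library size alone) and none fell, median 0.33, with MT-ND5 at 0.72 (SE 0.12) (camera adjusted p = 0.0287; adjusted p = 0.566 with an estimated correlation). Without control replicate 2 the median was 0.14 and the adjusted p 0.11, and without LMNB2 knockout replicate 1 they were 0.27 and 0.0574, in a range of 3.8e-10 to 0.137 for the adjusted p. Both tested blood markers rose, also adjusted over the list alone, ITGAM by 1.26 (SE 0.16) and CD68 by 0.63 (SE 0.11) (camera adjusted p = 0.0384; adjusted p = 0.379 with an estimated correlation), with 0.0671 without control replicate 1, 0.0621 without control replicate 2 and a range of 0.00772 to 0.0671. The other cell type markers gave values of 1.48 for ESAM (SE 0.36, adjusted p = 0.00709) and 0.73 for COL1A1 (SE 0.3, adjusted p = 0.0757). Each was the only tested gene of its list, with camera adjusted p values of 0.339 and 0.614 for these lists. ESAM stood at 1.3 with an adjusted p of 0.0728 without LMNB2 knockout replicate 2, in a range of 0.00757 to 0.0981 over the alternatives.

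The remaining lists did not pass in LMNB2 knockout. Of 22 lamina and envelope genes, 7 rose and 5 fell (8 and 6 adjusted over the list alone), with a median of 0.01 (camera adjusted p = 0.356), SYNE3 at 3.61 (SE 0.19) and TMPO, which encodes lamina-associated polypeptides, at -0.69 (SE 0.08). Of 22 p53 targets, 12 rose and 3 fell (4 adjusted over the list alone; camera adjusted p = 0.0795), with PMAIP1 at 1.04 (SE 0.1). With each chromosome's median removed this list passed (median 0.31, adjusted p = 0.0315, in a range of 0.00143 to 0.111 over the alternatives), and the cholesterol list reached 0.05 (median 0.23, range 0.00143 to 0.151). Adjusted p values were 0.0808 for cholesterol biosynthesis (8 rose and 2 fell, or 12 and 1 with library size alone; INSIG1 0.77, SE 0.08), 0.0901 for NF-kB targets (7 rose, 2 fell; IER3 1.09, SE 0.11) and 0.356 for YAP/TEAD and SRF targets (14 rose, 9 fell; FLNA 1.13, SE 0.09). They were 0.224 for the stress response (5 rose and 11 fell, or 7 and 7 with library size alone; CALR -0.79, SE 0.08), 0.7 for hypoxia and glycolysis (6 rose, 6 fell; SLC2A3 1.21, SE 0.09) and 0.6 for NRF2 targets (7 rose, 5 fell; ABCC3 2.22, SE 0.22). They were 0.7 for neuronal genes (5 rose, 5 fell; SYT1 1.20, SE 0.16) and 0.0897 for the lung lineage (2 rose, 2 fell; SOX9 1.66, SE 0.09). The actin list (12 rose, 4 fell; TMSB4X 1.73, SE 0.08) had an adjusted p of 0.0808, and of 0.0246 without control replicate 1, in a range of 0.0246 to 0.272. With library size alone the actin list also passed (median 0.31, camera adjusted p = 0.0278). Adjusting over the list alone added at most 2 genes called higher and 4 called lower to a list. With an estimated correlation no list passed, and the smallest adjusted p was 0.355. Signs of median and test differed for the hypoxia list (median 0.004) and neuronal genes (-0.13), and the median of the hypoxia list was -0.006 and that of the lamina list -0.002 with the relative log expression scaling, while the stress response list stood at 0.035 with library size alone.

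**Figure D2:**
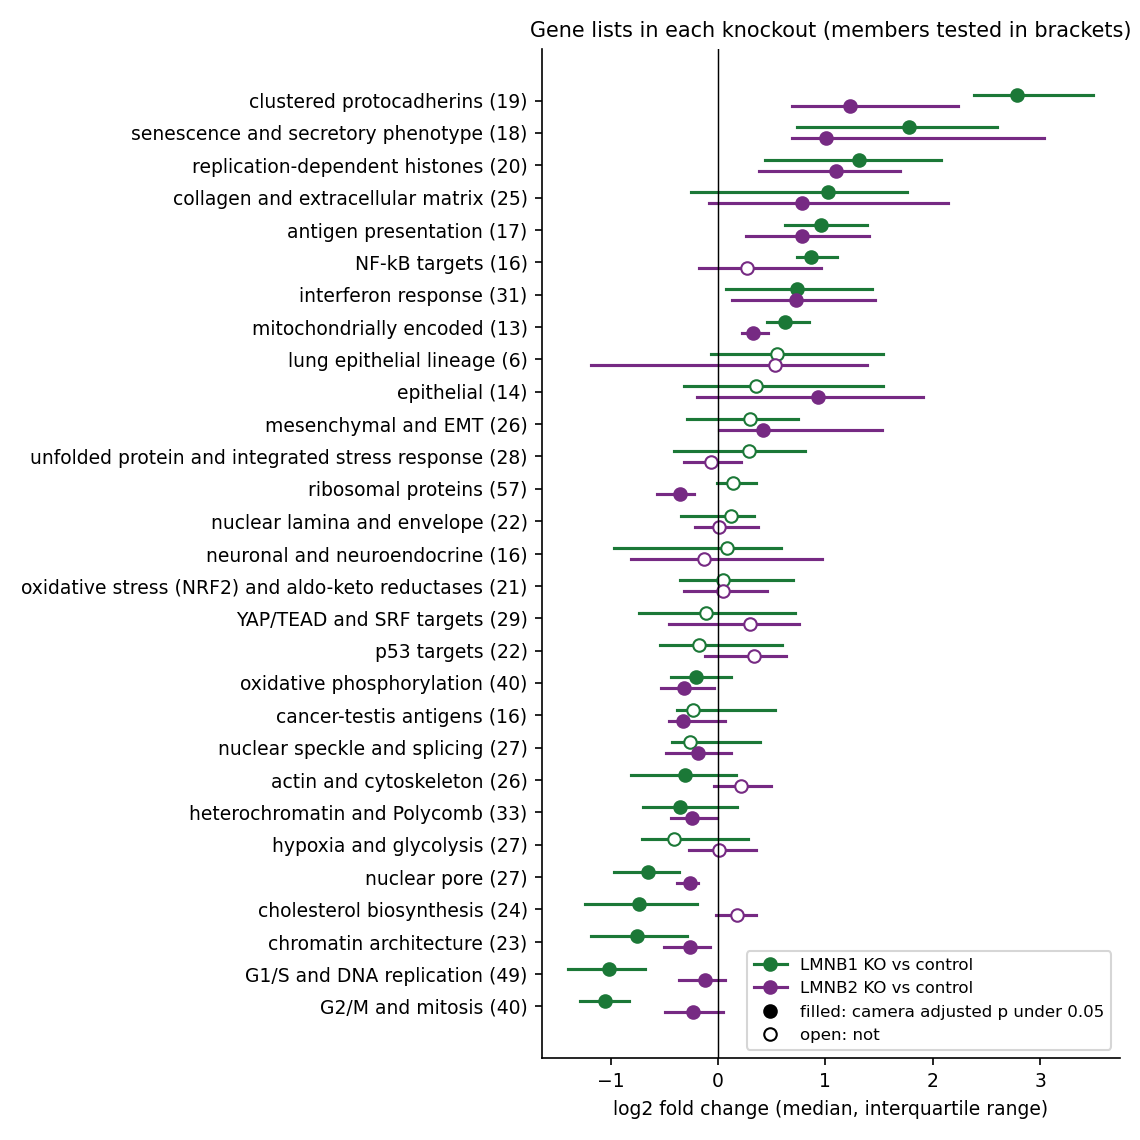
Median log2 fold change (points) and interquartile range (lines) of the members of each gene list with more than 2 tested genes, for LMNB1 knockout and LMNB2 knockout against control, with filled points at a camera adjusted p under 0.05. The G1/S list lay at -1.01 in LMNB1 knockout and at -0.12 in LMNB2 knockout, and the protocadherins at 2.79 and 1.23.

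LMNB1 knockout was compared directly with LMNB2 knockout to test where the knockouts differed. Of 49 G1/S and DNA replication genes, 43 were lower in LMNB1 knockout (44 adjusted over the list alone) and none higher, with a median of -0.99 (camera adjusted p = 2.2e-22; adjusted p = 0.0459 with an estimated correlation). Of 24 cholesterol biosynthesis genes, 18 were lower and 2 higher, also adjusted over the list alone, with a median of -0.93 (camera adjusted p = 4.52e-15; adjusted p = 0.0459 with an estimated correlation). Of 57 ribosomal protein genes, 47 were higher in LMNB1 knockout (49 adjusted over the list alone) and none lower, with a median of 0.60 (camera adjusted p = 4.76e-13; adjusted p = 0.698 with an estimated correlation). G2/M genes were lower in 33 of 40 cases and higher in 1, also adjusted over the list alone, median -0.84 (camera adjusted p = 1.73e-16; adjusted p = 0.416 with an estimated correlation). Actin and cytoskeleton genes were lower in 19 of 26 cases and higher in 3, also adjusted over the list alone, median -0.43 (camera adjusted p = 1.28e-06; adjusted p = 0.416 with an estimated correlation). Nuclear pore genes were lower in 17 of 27 cases (18 adjusted over the list alone) and higher in 3, median -0.38 (camera adjusted p = 0.00152; adjusted p = 0.698 with an estimated correlation). Chromatin architecture genes were lower in 11 of 23 cases and higher in 1 (12 and 3 adjusted over the list alone), median -0.38, or -0.22 without LMNB1 knockout replicate 2 (camera adjusted p = 0.00522; adjusted p = 0.757 with an estimated correlation). Protocadherins were higher in 12 of 19 cases and lower in none, also adjusted over the list alone, median 1.55 (camera adjusted p = 0.000395; adjusted p = 0.416 with an estimated correlation). The unfolded protein and integrated stress response list had 17 of 28 higher and 7 lower, also adjusted over the list alone, median 0.30 (camera adjusted p = 0.00316; adjusted p = 0.416 with an estimated correlation).

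Senescence and secretory genes were higher in LMNB1 knockout than in LMNB2 knockout in 10 of 18 cases and lower in 5, also adjusted over the list alone, median 0.70 (camera adjusted p = 0.00179; adjusted p = 0.558 with an estimated correlation). NF-kB targets were higher in 9 of 16 cases and lower in 2, also adjusted over the list alone, median 0.44 (camera adjusted p = 0.00654; adjusted p = 0.416 with an estimated correlation). With each chromosome's median removed their adjusted p values were 0.0598 (range over the alternatives 0.000417 to 0.0598) and 0.0611 (0.00265 to 0.0611). The remaining 21 lists did not pass, and the mitochondrially encoded list passed without control replicate 1 (median 0.21, adjusted p = 0.0353) and without control replicate 2 (0.21, adjusted p = 0.0261, range over the alternatives 0.0261 to 0.494). Median and mean differed in sign for the histone list (-0.05 and 0.10), antigen presentation (-0.09 and 0.19) and the collagen and matrix list (0.16 and -0.13), for each of which the test pointed upward. Of single genes, PLXNA2, a semaphorin receptor, was at least 55.7-fold higher in LMNB1 knockout, the matricellular gene CCN3 was higher by 5.82 (SE 0.32, adjusted p = 4.13e-07) and STAT6 by 5.05 (SE 0.19, adjusted p = 4.82e-08). GSPT2 had a count ratio of 134 (23.5 to 5320), and HBE1, uncertain as above, stood at 7.23 (SE 0.25). NTM was at least 38.3-fold lower and ZC4H2 at least 34.4-fold lower, and count ratios were 0.0177 (0.00212 to 0.0652) for CACNG4 and 0.0223 (0.00266 to 0.0826) for MFAP5. LMNA did not differ detectably, with 0.24 (SE 0.16, adjusted p = 0.252). Of 14829 genes, 7534 (50.8%) passed, 3673 higher and 3861 lower in LMNB1 knockout, and 2423 of them by at least 2-fold, 1209 higher and 1214 lower.

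Most genes called in both knockouts moved the same way. Of 4156 genes called in both, 3561 (85.7%) had the same direction, 1729 higher and 1832 lower, where independent lists would share 835.5 and 859.6. The other 595 went opposite ways, 318 and 277 in the respective directions. Across genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.538 (bootstrap interval 0.508 to 0.562 over 500 resamples), and 67.5% had the same sign. Both comparisons share the control libraries. Simulated unchanged groups against those controls gave a correlation of 0.532 (0.489 to 0.583 over 10 draws), a same-sign share of 66.9% and a mean of 0.6 genes called in the same direction in both. The covariance was 0.529 against 0.0487 simulated, a difference of 0.48. With each knockout set against a different control library, which was tried after these values were seen, 86% of the covariance of log2 CPM differences remained. Part of the excess may still come from the shared controls, since a deviation common to both control libraries would remain in that test. The number called in the same direction in both was 2135 without LMNB2 knockout replicate 2.

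**Figure D3:**
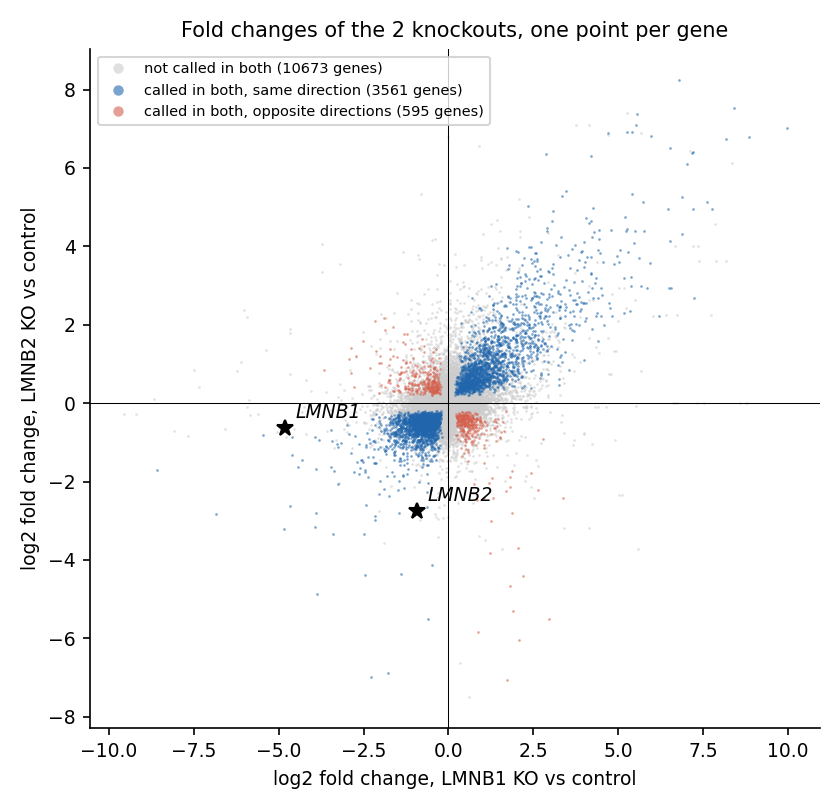
Log2 fold change against control of each tested gene in LMNB1 knockout (x) and in LMNB2 knockout (y), where genes with no read in a group carry fitted values that depend on the prior count. Of the 14829 genes, 3561 were called in the same direction in both, 595 in opposite directions, and the rest were not called in both.

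Genes of some chromosomes, or of parts of them, shifted relative to the rest. List members named above were chosen without regard to position, so those on a shifted chromosome may carry its shift. With each chromosome's median removed, 15, 17 and 9 lists passed in LMNB1 knockout, LMNB2 knockout and the direct comparison, against 16, 19 and 11. A median does not remove shifts of parts of a chromosome. In LMNB1 knockout the 221 tested genes of chromosome 18 had a median log2 fold change of -0.75, with 80.5% below 0, 145 called lower and 16 called higher (camera adjusted p = 1.33e-12; adjusted p = 0.102 with an estimated correlation). Every 10-Mb bin of its expressed genes lay below 0, with the bin from 0 Mb at -0.41 and that from 10 Mb at -1.01. Chromosome 9 also passed, with a median of 0.24 and 63.1% above 0 (adjusted p = 0.022; adjusted p = 0.0928 with an estimated correlation), and without control replicate 1 chromosomes 4, 8, 12 and 19 passed too, making 6 of 23 instead of 2. Chromosome 5 (median 0.23, adjusted p = 0.0556) passed without control replicate 2 (0.24, adjusted p = 0.0251) and without LMNB1 knockout replicate 2 (0.21, adjusted p = 0.0477). In LMNB2 knockout 10 chromosomes passed, and 3 with an estimated correlation (chromosomes 15, 9 and 7). Without control replicate 2 there were 5, with chromosomes 3, 5, 7, 13 and 16 no longer past, and chromosomes 7 and 13 were not past without LMNB2 knockout replicate 2 (adjusted p = 0.0522 and 0.059). Chromosome 15 had a median of 0.40, with 81.9% above 0, 243 called higher and 17 called lower (camera adjusted p = 9.8e-11; adjusted p = 0.0446 with an estimated correlation). Chromosome 10 had a median of -0.33, with 71.3% below 0, 241 called lower and 74 higher (camera adjusted p = 1.05e-06; adjusted p = 0.196 with an estimated correlation). Its bins from 0 to 30 Mb lay between -0.06 and 0.14, while those from 90 Mb on lay at -0.48, -0.80, -0.93, -0.88 and -0.94. Medians of the others were -0.28 for chromosome 8, 0.24 for 22, 0.20 for 16, 0.19 for 9, 0.13 for 7, -0.20 for 5, -0.18 for 3 and -0.16 for 13. Between the knockouts, chromosomes 18 (median -0.54, adjusted p = 1.58e-10), 15 (-0.47, 1.99e-09), 5 (0.38, 1.49e-07) and 10 (0.29, 0.000919) passed, with 0.145, 0.116, 0.301 and 0.452 as the adjusted p with an estimated correlation.

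**Figure D4:**
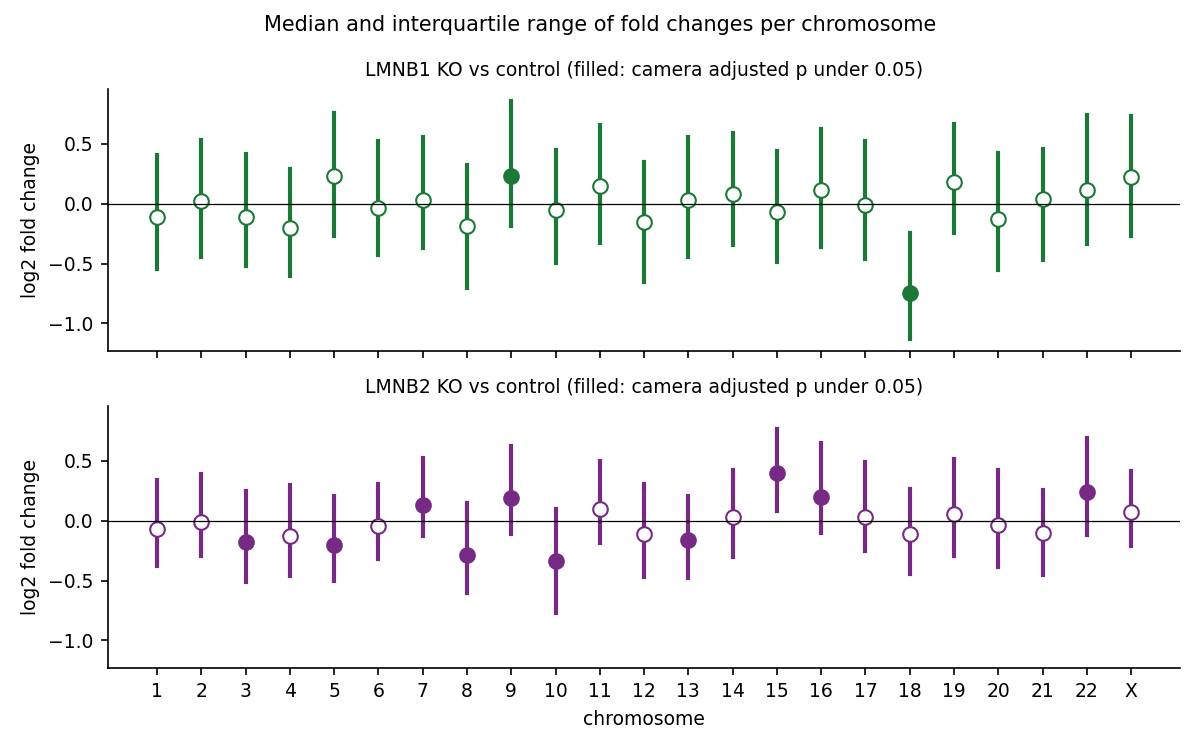
Median (points) and interquartile range (lines) of the log2 fold changes of the tested genes of each chromosome (1 to 22 and X) in LMNB1 knockout and LMNB2 knockout against control, with filled points at a camera adjusted p under 0.05. Chromosome 18 lay lowest in LMNB1 knockout at -0.75, and chromosome 15 highest in LMNB2 knockout at 0.40.

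Genes in gene-rich surroundings lay higher than those in gene-poor surroundings. Across 14693 genes, which are not independent replicates, the number of genes within 1 Mb correlated with the log2 fold change with a Spearman coefficient of 0.14 in LMNB1 knockout and 0.16 in LMNB2 knockout. With each chromosome's median subtracted the coefficients were 0.096 and 0.10. Medians went from -0.12 for a neighbourhood of up to 12 genes to 0.16 for one of 43 or more in LMNB1 knockout, and from -0.12 to 0.11 in LMNB2 knockout. Between the knockouts the coefficient was 0.02. Both comparisons with control share the same control libraries, so a deviation of those libraries linked to gene density would give both values. Set against the authors' deposited table of LMNB1 knockout, which lists 4444 protein-coding genes with 1997 higher and 2447 lower, 4384 (98.6%) were called here in the same direction. Of the 3020 genes in the authors' deposited table of LMNB2 knockout (1478 higher, 1542 lower), 2919 (96.7%) were. The log2 fold changes in the authors' deposited tables correlated with those here with Pearson coefficients of 0.993 and 0.995 across genes. The deposited tables come from the same experiment, also through edgeR, and hold no small changes. High shares and coefficients were thus nearly fixed in advance and are no independent support. The authors' deposited tables gave -4.80 for LMNB1 in its knockout and -2.76 for LMNB2 in its own.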

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

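Of the tests below, those of the G2/M median, of the share of genes called in the same direction and of the split of the control libraries were chosen only after the result was seen, and the median shifts of the chromosomes and lists and the number of genes called in both knockouts were known when the other tests were written. The results named first stood out because the direct test of LMNB1 knockout against LMNB2 knockout passed at camera's preset correlation. With an estimated correlation only the G1/S and cholesterol lists passed (adjusted p = 0.0459 each), while the other lists had adjusted p values of 0.416 to 0.757 and the chromosomes of 0.116 to 0.452. With each chromosome's median removed, the senescence list had 0.0598 (range over the alternatives 0.000417 to 0.0598) and the NF-kB list 0.0611 (0.00265 to 0.0611).

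Gene lists with a lower median in LMNB1 knockout than in LMNB2 knockout were G1/S and DNA replication (-0.991), cholesterol biosynthesis (-0.931), G2/M (-0.835), actin and cytoskeleton (-0.427), nuclear pore (-0.384) and chromatin architecture (-0.375). Lists with a higher median were the protocadherins (1.552), senescence and secretory genes (0.704), ribosomal proteins (0.596), NF-kB targets (0.437) and the unfolded protein and integrated stress response (0.305). Of the chromosomes, 18 (-0.542) and 15 (-0.466) were lower in LMNB1 knockout and 5 (0.382) and 10 (0.289) higher.

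Chromosome shifts were weighed against a copy-number difference between the cells sampled and against detachment of gene-poor chromatin from the lamina. Of expressed genes, 85.3% of 191 on chromosome 18 were lower in LMNB1 knockout (51% on the other chromosomes), 82.2% of 438 on chromosome 15 were higher in LMNB2 knockout (46.5% on the others) and 75.1% of 485 on chromosome 10 were lower there (51.4% on the others). These shares restate the shifts that prompted the test, so copy number cannot be told apart from other causes, and DNA was not analysed here. The gene-poor part minus the gene-dense part gave -0.042 on chromosome 15 (bootstrap interval -0.173 to 0.074 over 2000 resamples), 0.134 on chromosome 10 (0.009 to 0.238) and 0.189 on chromosome 18 (-0.067 to 0.353). Detachment was taken to shift the gene-poor part further by at least 0.3 in each chromosome's own direction. That is upward on chromosome 15 and downward on 10 and 18, and no interval reached it. On 10 and 18 the estimates lay on the opposite side, and the interval of 18 passed 0.3 there, which the bound written beforehand had also left open. Detachment that raises gene-poor genes was not tested on 10 and 18, so it stays open there.

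The lower cell cycle lists in LMNB1 knockout were weighed against cells further into S phase or G2, a lower share of cycling cells, and scaling. The G2/M median of -1.052 argues against a larger share of cells in G2. It is itself part of the pattern and need not rise in S phase, so cells further into S phase stay open. Library size alone moved the median of all genes by only 0.049 and left the G1/S median at -0.965. The choice between these scalings therefore mattered little. The bound for scaling could hardly have been met, so scaling in general was not tested. The interquartile range of the G2/M members was 0.454, under the 0.6 set in advance for a lower share of cycling cells. The quartiles of the G1/S members, at -1.394 and -0.678, lay further apart than that. Those of the ribosomal protein list, at -0.006 and 0.357, lay closer together. A narrow range is therefore not particular to the cell cycle lists, and a lower share of cycling cells stays open. A direct effect of lamin B1 on these genes was not tested and stays open.

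The genes called in the same direction in both knockouts were weighed against chance from the shared controls, common copy-number differences, and selection or passage. Simulated unchanged groups gave a mean of 0.6 such genes, against 3561, but unchanged groups give next to no calls whatever the controls, so the bound written beforehand was wrong and this number decides nothing. With each knockout set against a different control library, 86% of the covariance of log2 CPM differences remained (bootstrap interval 84.6 to 87.3%), short of the 90% required, so chance values of single control libraries stay open as part of the cause, as do deviations common to both. The covariance of the fold changes kept 97.4% of its value after each chromosome's median was subtracted, so shifts of whole chromosomes made up little of it. The chromosome medians were known beforehand, which largely fixed this outcome. A median does not remove differences of parts of a chromosome, so common copy-number differences of such parts stay open. Selection or passage cannot be told apart from loss of a B-type lamin, since no edited cells with intact lamin genes are in the design, and the 85.7% called in the same direction would arise under both.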

How the results depend on the processing

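Alternatives added only after the data were seen were the crossed control numbers and the removal or subtraction of chromosome medians. No value of a named gene, list, chromosome or summary changed direction while called under any alternative run. Of 2122 values of 235 named gene results 18 lost and 1 gained a call, of 1248 values of 96 list results 79 lost and 35 gained one, and of 621 values of 69 chromosome results 20 lost and 20 gained one. With an estimated correlation, 0, 0 and 2 lists passed in LMNB1 knockout, LMNB2 knockout and the direct comparison, against 16, 19 and 11. That test takes in the residual correlation of a list's members, here from 3 residual degrees of freedom. The ranges over the alternatives given for lists leave it out. With fry 22, 25 and 19 passed, and fry does not compare a list with other genes. Fry ended the calls of the oxidative phosphorylation (adjusted p = 0.0755, range over the alternatives 0.000887 to 0.275) and mitochondrially encoded (0.0603, 3.11e-11 to 0.0603) lists in LMNB1 knockout, and in LMNB2 knockout those of the chromatin architecture (0.0513, 6.83e-05 to 0.0513), ribosomal protein (0.0547, 2.12e-29 to 0.0547) and mitochondrially encoded (0.137, 3.8e-10 to 0.137) lists. In LMNB2 knockout the G1/S and speckle lists were no longer past with library size alone, the stricter filter or chromosome medians removed, nor were the protocadherins with the first 2, the epithelial list with the last 2, the heterochromatin list with library size alone or the blood markers with chromosome medians removed. Chromosomes past the threshold with an estimated correlation were 0, 3 and 0 against 2, 10 and 4, and with expressed genes only 5 in LMNB1 knockout.

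A 2-fold threshold left 2872, 1699 and 2423 calls by its own construction. Leaving out 1 library at a time, with 2 residual degrees of freedom and the lone sample assumed to vary like the other groups, gave 6235 to 8383, 3541 to 6859 and 5345 to 8740 calls. The lowest LMNB2 knockout values came without LMNB2 knockout replicate 2 (3541) and replicate 1 (4080). The same fits gave LMNB1 at -4.893 to -4.722 and LMNB2 at -2.883 to -2.644 in their own knockouts, 16 to 17, 15 to 19 and 11 to 12 lists, and 2 to 6, 5 to 14 and 4 to 5 chromosomes. They gave a correlation between knockouts of 0.467 to 0.644 and 2135 to 4178 shared calls. Spearman's coefficient of that agreement was 0.478, against a Pearson coefficient of 0.538, and the Pearson coefficient was 0.543 with chromosome medians subtracted. The cause was not tested. DESeq2 called 6106, 4196 and 5258 genes, and the other tools, filters and scalings lay closer to the values in the report. The density coefficients with chromosome medians subtracted were 0.096, 0.10 and 0.03.

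The replicate block gave 7446, 5427 and 6854 calls, of which 7412, 5401 and 6823 were also called without it. Among lists and named genes it ended only the call of the speckle list in LMNB2 knockout (adjusted p = 0.056, range over the alternatives 0.0299 to 0.256), and chromosomes were not tested with it. Deviations of libraries with the same number correlated at -0.139, -0.08 and 0.116 between groups, too weak to show or exclude a pairing by number. With the control numbers crossed in the block, 8804, 7264 and 8418 genes were called, against 8001, 6283 and 7534 without a block. A pairing under other numbers therefore stays open. Depth limits genes with few counts, for which only bounds or wide count ratios could be given.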

Other observations

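All stretches and genes in this part were chosen after their values were seen, and are given as values. On chromosome X, all 8 tested genes from 63347228 to 65741931, ZC4H2 included, were called lower in LMNB1 knockout, against 4025 of all 14829 genes. Among them were SPIN4 (log2 fold change -1.35, SE 0.15), AMER1 (-1.67, SE 0.22), a regulator of WNT signalling, LAS1L (-0.97, SE 0.09) and MSN (-0.90, SE 0.09), which encodes moesin. MTMR8 had a count ratio of 0.0738 (95% interval 0.00852 to 0.293), and ZC3H12B, with no read in LMNB1 knockout, was at least 3.22-fold lower. In LMNB2 knockout AMER1 (-1.17, SE 0.21) and LAS1L (-0.38, SE 0.09) were called lower and MSN (0.37, SE 0.09) higher. On chromosome 11, 5 of 7 tested genes from 5253190 to 5938619, a stretch with the globin genes HBG2 and HBE1, the olfactory receptor genes OR51B4 and OR51B5, and TRIM34 and TRIM5, were called lower in LMNB2 knockout, and in LMNB1 knockout 5 were called higher and 2 lower. The annotated extents of several of these overlap, so their reads cannot be told apart.

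Some genes were called in opposite directions in the knockouts. The matricellular gene CCN3 stood at 3.39 (SE 0.24) in LMNB1 knockout and -2.42 (SE 0.46) in LMNB2 knockout, PRDM8 at 1.29 (SE 0.12) and -1.91 (SE 0.14), the adhesion receptor gene ADGRB1 at 1.87 (SE 0.2) and -1.73 (SE 0.27), and the synaptic vesicle priming gene UNC13A at 1.81 (SE 0.26) and -2.13 (SE 0.38). The creatine synthesis gene GATM stood at -1.62 (SE 0.37) and 1.94 (SE 0.25), the kinase gene WNK4 at -1.72 (SE 0.19) and 1.38 (SE 0.14), THSD1 at -1.33 (SE 0.22) and 1.55 (SE 0.17), and the smooth muscle actin gene ACTA2 at -1.63 (SE 0.27) and 1.21 (SE 0.2).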
